A study of Mus musculus with 24 samples.

How the data were processed

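Joint gene expression and chromatin accessibility libraries had been prepared from flash-frozen prefrontal cortex of C57BL/6 mouse pups on the 10x Multiome platform, per the labels. The pups were held in 85% oxygen or in room air from postnatal day 1 to postnatal day 14, and the cortex was dissected on postnatal day 14. There were 4 groups of 3 mice: hyperoxia females, room air females, hyperoxia males and room air males. The 12 gene expression samples were used, and the 12 chromatin accessibility samples were not analysed here. The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and nucleus, whole numbers without scaling. The authors' tools, per the submitters' processing notes, were Cell Ranger ARC, Seurat and Signac, with the mm10 genome build; their versions, the aligner and the gene annotation are not given in the sources used here. In the male hyperoxia samples the mouse tags in the library names and in the deposited matrices are in a different order, which leaves the groups as they are. It leaves open which male hyperoxia mouse is meant by number 1, 2 or 3, and so bears on the fit with a block for the mouse number, on the correlations of mice of equal number and on the name of the male hyperoxia mouse left out.

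The deposited matrices held 25086 genes. Deposited nuclei per mouse numbered 1578, 2580 and 2538 in hyperoxia females, 2082, 1565 and 3427 in room air females, 2111, 2377 and 2553 in hyperoxia males, and 2290, 2572 and 2050 in room air males. Total UMI counts per mouse were 24889485 to 56324029. The median nucleus of a mouse had between 13536 and 20564 UMIs and between 4010 and 4902 genes. A filter at 500 genes and 5% mitochondrial counts removed no nucleus, because the deposited nuclei of every mouse reached at most 2.43% to 2.47% mitochondrial counts. Simulated doublet scores were used to remove 20 to 94 nuclei per mouse, at 0.8% per 1000 nuclei. Counts were normalised per nucleus and clustered with scanpy 1.11.5 and leidenalg 0.10.2 in Python 3.11.15, with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and clusters were named from marker genes. Clusters with a high doublet score or with markers of more than 1 class (mixed), and clusters without a name, were kept out of the tests. Xist was at 1436 to 1574 CPM (counts scaled to a fixed library size) in the female mice and at 0.0967 to 3.83 in the male mice. Uty was at 200 to 229 CPM in males and at most 0.148 in females, so the sex of every mouse was as labelled. Libraries of the same group were compared in pairs, and no 2 of them held the same values. Across groups the numbers of deposited nuclei differed between all mice.

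Counts were summed per mouse and class (pseudobulk), using each class with at least 20 nuclei in a mouse and at least 2 mice per group. Each mouse is 1 replicate. The 4 groups were fitted together in edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood test, limma 3.58.1, R 4.3.3), and the adjusted p of a gene is the Benjamini-Hochberg value over the genes of its class and comparison. A gene was called past adjusted p 0.05. The comparisons were hyperoxia minus room air in females, the same in males, the average of the 2, the difference between them (male minus female), and male minus female in room air. Log2 differences are given with the standard error (SE) of the fit, and the mean CPM per group is given with its SD over mice. Genes on the sex chromosomes that check the labels were not counted as calls. The shares of nuclei per class were compared on the logit scale with exact permutation tests over mice, of 400 arrangements for the average and of 20 within a sex, where the smallest p is 0.1. In a trial, new counts were drawn from a model with the dispersion trend of the data, and some genes were changed by known amounts. The changed genes had a mean of at least 20 counts per mouse, so genes with fewer counts were not tried. The edgeR test on the average recovered 98% of genes changed by a log2 of 1 and 67% of those changed by 0.5 in excitatory nuclei. In astrocytes it recovered 97% and 39%. For the difference between sexes it recovered 73% and 18% in excitatory nuclei, and 37% and 2% in astrocytes. For the share test, logit shares were drawn directly, without counts, with an SD of 0.15 between mice. The share test found 100% of simulated logit differences of 0.8 and 6.5% of the unchanged cases. That SD was not taken from the data, so the trial gives no power for classes that vary more between mice. The observed differences in the average were smaller than 0.8 (oligodendrocytes −0.332), and the power at such sizes was not tested.

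Lists of genes with a shared role were fixed before the data were examined: targets of hypoxia inducible factor (HIF), antioxidant genes of NRF2, p53 targets, nuclear genes of oxidative phosphorylation, the unfolded protein response, heat shock, myelin, cholesterol synthesis, immediate early genes, glucocorticoid response and circadian clock. Others were glutamate synapse, GABA synapse, perineuronal net and matrix, neuronal immaturity, interferon response, microglial activation, reactive astrocyte, vascular growth, proliferation, potassium channels and excitability, axon guidance and adhesion, mitochondrial transcripts and cytosolic ribosomal proteins. The last list was taken by name and so also holds the Rps6ka kinases. The markers of the other classes were tested in the same way. Lists with at least 8 measured members were tested with camera at a preset correlation of 0.01 between genes, and adjusted over the 169 tests of a comparison. Camera with a correlation estimated from the mice called no list in any comparison, and that adjusted p is printed beside called lists. A trial in which HIF targets were raised by 0.3 in astrocytes gave them an adjusted p of 3.44e-17, and 1 of the 24 other lists was called as well. The trial drew each gene on its own, without correlation between genes, so it gives no rate of false calls for the real counts. In the real counts, exchanging treatment labels within each sex gave up to 74 called lists. Genes of the 8 classes were picked by a fixed rule: for each class and comparison the 2 smallest p values higher and the 2 lower among calls, without predicted, mitochondrial or ribosomal genes, plus up to 3 called members of each list. Others are named for being called in several classes or in a subtype, or as markers. Some genes that the rule picks are not reported here.

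Alternatives fixed in advance were other size factors (RLE), DESeq2 1.42.0, limma-voom with sample weights, no expression filter, all deposited nuclei with doublets, and nuclei with at least 1000 genes and at most 1% mitochondrial counts. Further ones were every mouse thinned to the same number of nuclei, genes of other cells left out, a block for the mouse number, only the groups compared, fry and an estimated correlation for lists, other denominators for shares, and each mouse left out in turn. A mitochondrial covariate and a fit without the 2 mice with the highest mitochondrial share (room air female mouse 2 and room air male mouse 1) were chosen after the data were seen, as were shares among excitatory and inhibitory neurons alone. Gene positions are on GRCm38, 1-based, from RefSeq, and matplotlib 3.10.9 drew the figures.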

Results

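Nuclei from the prefrontal cortex at postnatal day 14 were grouped into neurons, macroglia, microglia and vascular cells. Excitatory neurons were the largest class with 13418 nuclei, followed by astrocytes (2236), inhibitory neurons (2179), oligodendrocyte precursor cells (OPCs, 1914), oligodendrocytes (1758) and microglia (1304), and there were 307 endothelial and 309 mural or fibroblast nuclei. Nuclei with the markers of striatal projection neurons made up 0.58%, 3.21% and 4.14% of the nuclei kept in hyperoxia females and 1.27%, 1.17% and 1.92% in room air females. They made up 1.3%, 0.64% and 0.64% in hyperoxia males and 2.94%, 3.61% and 1.69% in room air males. The median mitochondrial percentage of counts was 0.202, 0.24 and 0.28 in hyperoxia females, 0.597, 0.939 and 0.251 in room air females, 0.354, 0.574 and 0.119 in hyperoxia males, and 0.842, 0.407 and 0.154 in room air males.

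Oligodendrocytes, the myelin-forming cells, made up 6.11 ± 1.33% (SD, n = 6) of named nuclei in hyperoxia and 8.26 ± 1.31% (SD, n = 6) in room air, and 5 of 6 hyperoxia mice lay below the mean of their own sex in room air. The exact permutation p was 0.035, and adjusted over the 8 classes it was 0.28, so the share of no class changed past the threshold. Among non-neuronal nuclei alone the logit difference of oligodendrocytes was −0.339 with an exact p of 0.005, adjusted 0.04. Excitatory neurons made up 53.4 ± 2.74% (SD, n = 3) in hyperoxia females against 59.0 ± 5.14% (SD, n = 3) in room air females. They made up 59.8 ± 3.07% (SD, n = 3) in hyperoxia males against 50.9 ± 6.44% (SD, n = 3) in room air males. The exact p for that difference between the sexes was 0.025, and its adjusted value was 0.2. Among neurons alone, striatal and immature neurons included, the logit difference between the sexes was 0.607 with an exact p of 0.005, adjusted 0.04. Among excitatory and inhibitory neurons alone it was 0.314 with an exact p of 0.015, adjusted 0.06, and did not pass. Part of it thus goes with striatal and immature neurons, which were left out together. Among the 13 neuronal subtypes the smallest exact p was 0.015, for layer 6 corticothalamic (L6 CT) neurons in the difference between the sexes, with an adjusted value of 0.195. Within a sex no exact p was below 0.1.

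**Figure D1:**
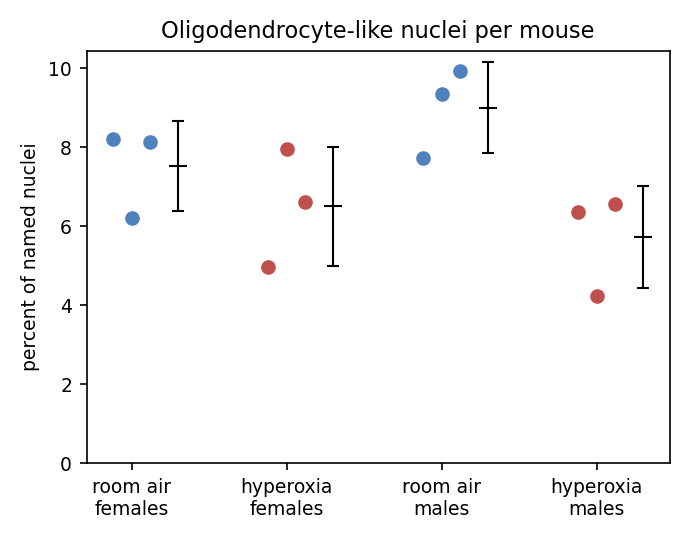
Oligodendrocyte nuclei as a percentage of the named nuclei of each mouse (points), with the mean and SD of the 3 mice of each group beside them. The mean over both sexes was 6.11% in hyperoxia and 8.26% in room air.

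Averaged over the sexes, hyperoxia minus room air gave 4441 calls over the 6 classes with any call, 2491 higher and 1950 lower. Excitatory neurons had 1465 higher and 1418 lower, inhibitory neurons 300 and 200, astrocytes 315 and 163, oligodendrocytes 203 and 91, OPCs 176 and 65, and microglia 32 and 13. The classes differed in nuclei and in precision, with a median SE of 0.0966 in excitatory neurons and 0.226 in microglia. The counts therefore do not rank the classes by the size of their response. Without hyperoxia female mouse 2 the count was 2663, without hyperoxia female mouse 3 it was 2832, and without room air female mouse 3 it was 2892. DESeq2 gave 3933 calls, of which 3643 were shared. Of 169 list tests 73 were called, 35 higher and 38 lower, and 0 were called with an estimated correlation.

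**Figure D2:**
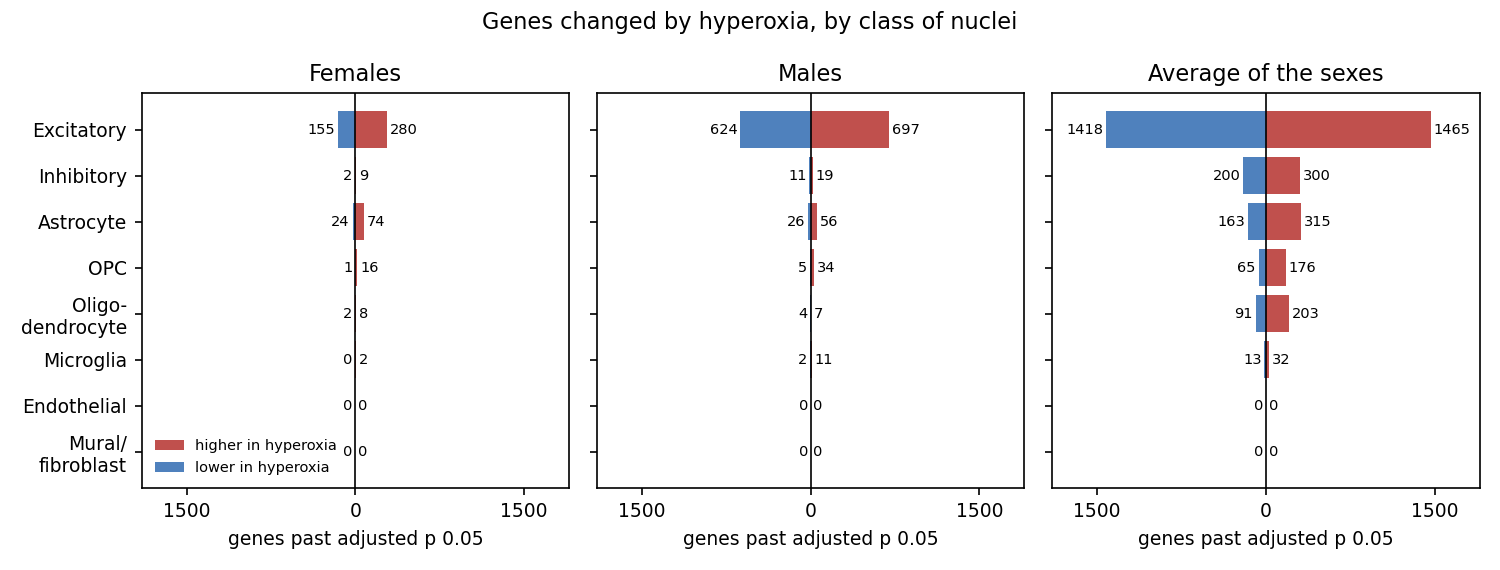
Genes higher and lower past adjusted p 0.05 in each class for each comparison of hyperoxia with room air. Excitatory neurons had the most calls in each, with 1465 higher and 1418 lower in the average over the sexes. They also had the most nuclei, and the counts depend on nuclei and precision.

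In excitatory neurons the gene with the smallest p was Myo16, which encodes an unconventional myosin of neurons that acts on the actin cytoskeleton (chromosome 8, 10153911 to 10634742). Myo16 rose by a log2 of 0.47 (SE 0.039, adjusted p = 9.24e-06). The level of Myo16 went from 184 ± 7.46 CPM (SD, n = 3) to 228 ± 4.59 (SD, n = 3) in females and from 174 ± 7.72 (SD, n = 3) to 271 ± 9.14 (SD, n = 3) in males. Adamts2, a protease that processes procollagen (chromosome 11, 50602085 to 50807573), rose by 0.55 (SE 0.054, adjusted p = 4e-05). Ostc, a subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum (chromosome 3, 130695917 to 130709444), fell by 0.68 (SE 0.06, adjusted p = 1.84e-05). The level of Ostc went from 23.7 ± 0.98 CPM (SD, n = 3) to 16.9 ± 1.67 (SD, n = 3) in females and from 22.8 ± 0.171 (SD, n = 3) to 12.6 ± 0.691 (SD, n = 3) in males. Taf13, a subunit of the general transcription factor TFIID (chromosome 3, 108571699 to 108582068), fell by 0.71 (SE 0.082, adjusted p = 0.000137). Each of these genes moved the same way in 6 of 6 hyperoxia mice against the room air mean of their sex.

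**Figure D3:**
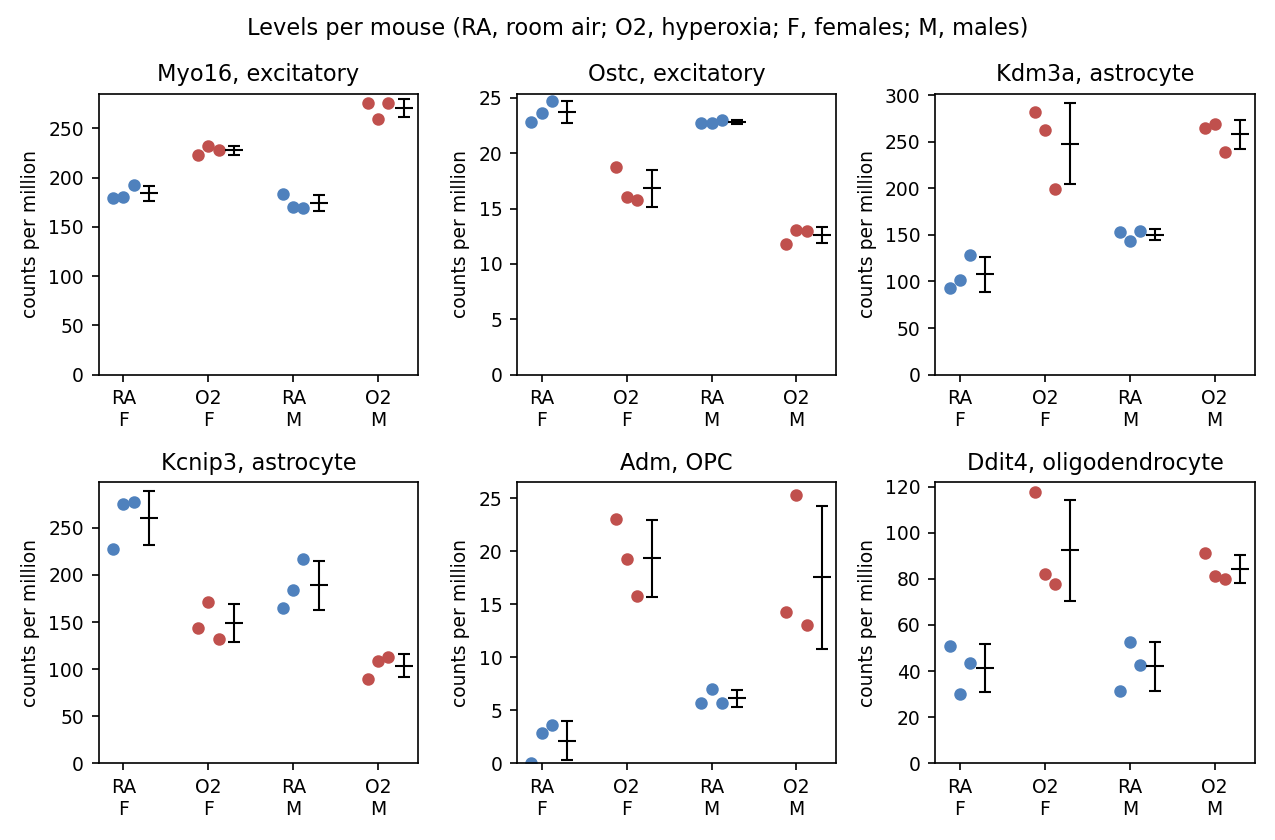
CPM per mouse (points) with the mean and SD of the 3 mice of each group, for Myo16 and Ostc in excitatory neurons, Kdm3a and Kcnip3 in astrocytes, Adm in OPCs and Ddit4 in oligodendrocytes. For every gene 6 of 6 hyperoxia mice lay beyond the room air mean of their sex.

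The list of protein folding and the unfolded protein response was called lower in excitatory neurons, with 9 of 20 members lower over all genes and 10 lower and 1 higher when adjusted over the list alone (adjusted p = 0.000572, and adjusted p = 0.416 with an estimated correlation). The chaperone genes Hsp90b1, Pdia4 and Hspa5 fell by 0.33 (SE 0.049, adjusted p = 0.00061), 0.58 (SE 0.093, adjusted p = 0.00117) and 0.30 (SE 0.049, adjusted p = 0.00133). In inhibitory neurons 1 of 19 members fell over all genes and 7 over the list alone (adjusted p = 0.00443, and adjusted p = 0.268 with an estimated correlation). Hspa5 fell by 0.31 (SE 0.072, adjusted p = 0.0196). Cholesterol genes in excitatory neurons were not called as a list (adjusted p = 0.0941), although 6 of 23 members fell, among them Msmo1 by 0.35, Nsdhl by 0.47 and Srebf2 by 0.21. Immediate early genes, which follow neuronal activity, had a median of −0.503 over 25 members in excitatory neurons (adjusted p = 0.000878, and adjusted p = 0.662 with an estimated correlation). Npas4 fell by 0.75 (SE 0.214, adjusted p = 0.0433), Nptx2 fell by 0.34, and Klf2 rose by 0.72. In inhibitory neurons 0 of 19 immediate early genes passed the threshold, with a median of −0.229 (adjusted p = 0.0342, and adjusted p = 0.662 with an estimated correlation).

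Lists of synapse and ion channel genes were called higher in excitatory neurons. Longer genes rose more in general, as given under other observations. Whether these lists rose beyond that trend, here or in other classes, was not tested. Of the glutamate synapse genes 8 of 31 rose and 1 fell over all genes, and 15 rose and 3 fell over the list alone (adjusted p = 0.000388, and adjusted p = 0.6 with an estimated correlation). The NMDA receptor subunit Grin1 rose by 0.29 (SE 0.056, adjusted p = 0.00335), the kinase gene Camk2b by 0.21 and the AMPA receptor subunit Gria1 by 0.22. Of the GABA synapse genes 7 of 24 rose and 1 fell, and over the list alone 9 rose and 1 fell (adjusted p = 0.00443, and adjusted p = 0.61 with an estimated correlation). The receptor subunit gene Gabra3 rose by 0.27 and the scaffold gene Gphn by 0.24. Of the potassium channel and excitability genes 8 of 26 rose and 1 fell, with 12 and 1 over the list alone (adjusted p = 0.000108, and adjusted p = 0.324 with an estimated correlation). Among them Kcnn3 rose by 0.56 and Kcnt2 by 0.28. Axon guidance and adhesion genes had 12 of 34 higher and 1 lower, and 13 and 1 over the list alone (adjusted p = 0.00155, and adjusted p = 0.6 with an estimated correlation). Sema6d (0.23), Plxna2 (0.25) and Plxna4 (0.24) were among them.

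The list of immature neurons was also called higher in excitatory nuclei, where 4 of 19 rose and 1 fell over all genes and 5 and 1 over the list alone (adjusted p = 0.0284, and adjusted p = 0.662 with an estimated correlation). The microtubule gene Dcx rose by 0.32 (SE 0.053, adjusted p = 0.00145), Dpysl3 by 0.37 (SE 0.063, adjusted p = 0.00149) and Igfbpl1 by 0.69 (SE 0.138, adjusted p = 0.00399). The matrix proteoglycan gene Vcan rose by 0.54 (SE 0.07, adjusted p = 0.000303). Genes that respond to glucocorticoids were not called as a list (adjusted p = 0.826), but Hif3a rose by 0.88 (SE 0.111, adjusted p = 0.000227) and Fkbp5 by 0.48 (SE 0.14, adjusted p = 0.0394). Of the clock genes, which were not called as a list (adjusted p = 0.379), Hlf rose by 0.47 (SE 0.056, adjusted p = 0.000137) and Nr1d1 by 0.49 (SE 0.107, adjusted p = 0.0064), and Per2 fell by 0.29 (SE 0.069, adjusted p = 0.01).

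Myelin genes fell in excitatory nuclei, 9 of 24 over all genes and 10 lower and 1 higher over the list alone (adjusted p = 0.000655, and adjusted p = 0.527 with an estimated correlation). Mog, a myelin surface protein gene (chromosome 17, 37010740 to 37023398), fell by 1.09 (SE 0.136, adjusted p = 0.000201), Mal fell by 1.14 (SE 0.206, adjusted p = 0.00225) and Cldn11 fell by 0.76 (SE 0.142, adjusted p = 0.00263). These are oligodendrocyte genes at low levels in neurons: Mog was at 3.62 ± 0.805 CPM (SD, n = 3) in room air females and 1.91 ± 0.147 (SD, n = 3) in hyperoxia females. The markers of oligodendrocytes moved with them in the same nuclei, 7 of 20 lower and 1 higher (adjusted p = 0.000904, and adjusted p = 0.527 with an estimated correlation). Microglial activation genes, of which 2 of 14 fell (Cd9 by 0.61, Ctsd by 0.23), were lower in excitatory nuclei too (adjusted p = 0.034, and adjusted p = 0.627 with an estimated correlation). The markers of inhibitory neurons were higher there, 2 of 13 over all genes (adjusted p = 0.0114, and adjusted p = 0.61 with an estimated correlation). Of the markers of immature neurons 3 of 10 were higher (adjusted p = 0.0284, and adjusted p = 0.61 with an estimated correlation).

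In inhibitory neurons the kinase gene Pak3, which acts on dendritic spines (chromosome X, 143518366 to 143797796), rose by 0.45 (SE 0.057, adjusted p = 0.00025). Dpp10, an auxiliary subunit of A-type potassium channels (chromosome 1, 123332138 to 124845815), rose by 0.56 (SE 0.07, adjusted p = 0.00025). Spink10, a gene of the Kazal-type protease inhibitor family (chromosome 18, 62548873 to 62664341), fell by 0.91 (SE 0.102, adjusted p = 7.37e-05), and the amino acid transporter gene Slc38a2 fell by 0.54 (SE 0.081, adjusted p = 0.00155). All 4 genes moved the same way in 6 of 6 hyperoxia mice. Glutamate synapse genes rose here too, 5 of 30 over all genes and 12 over the list alone (adjusted p = 8.24e-08, and adjusted p = 0.269 with an estimated correlation). GABA synapse genes rose as well, 5 of 24 over all genes and 10 over the list alone (adjusted p = 0.000465, and adjusted p = 0.269 with an estimated correlation). Grin1 rose by 0.27 and Gad2, which makes GABA, by 0.30. Potassium channel genes had 5 of 26 higher and over the list alone 14 higher and 2 lower (adjusted p = 4.04e-07, and adjusted p = 0.175 with an estimated correlation). Axon guidance genes had 4 of 34 higher, and 11 higher and 1 lower over the list alone (adjusted p = 5.01e-06, and adjusted p = 0.178 with an estimated correlation). Dcx rose by 0.39 and Gap43 by 0.43 in a list of 17 immature neuron genes with 2 higher and 1 lower, and 5 and 1 over the list alone (adjusted p = 0.00286, and adjusted p = 0.627 with an estimated correlation).

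In astrocytes Kdm3a, a histone demethylase gene and a HIF target (chromosome 6, 71588970 to 71632990), rose by 0.98 (SE 0.096, adjusted p = 1.41e-07). The level of Kdm3a went from 108 ± 18.9 CPM (SD, n = 3) to 248 ± 43.5 (SD, n = 3) in females and from 150 ± 5.73 (SD, n = 3) to 258 ± 16 (SD, n = 3) in males. Fam171a1, a membrane protein gene (chromosome 2, 3114224 to 3227806), rose by 0.88 (SE 0.098, adjusted p = 1.37e-06). Kcnip3, a calcium-binding partner of potassium channels (chromosome 2, 127456498 to 127522094), fell by 0.84 (SE 0.096, adjusted p = 1.73e-06), and the kinase gene Nim1k fell by 0.61 (SE 0.085, adjusted p = 2.67e-05). The clock gene Bhlhe40 rose by 1.10 (SE 0.144, adjusted p = 1.98e-05) and the p53 target Trp53inp1 by 0.93 (SE 0.145, adjusted p = 0.000234). The intermediate filament gene Gfap, a member of the reactive astrocyte list, rose by 0.60 (SE 0.154, adjusted p = 0.0217). That list as a whole was not called in astrocytes. Dusp6, a brake on ERK signalling, fell by 0.91 (SE 0.191, adjusted p = 0.00397), and the receptor subunit gene Cacng8 fell by 0.76 (SE 0.139, adjusted p = 0.00105). The first 4 of these genes and Bhlhe40 moved the same way in 6 of 6 hyperoxia mice.

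Lists of metabolism and stress hormones moved in astrocytes. HIF targets had 6 of 19 higher over all genes and 8 over the list alone (adjusted p = 1.35e-05, and adjusted p = 0.404 with an estimated correlation). Among them were the glycolysis gene Eno1 (0.50) and Pdk1 (0.69), whose product inhibits pyruvate dehydrogenase. Glucocorticoid response genes had 6 of 16 higher and 10 over the list alone (adjusted p = 1.52e-07, and adjusted p = 0.454 with an estimated correlation). The metallothionein genes Mt2 and Mt1 rose by 0.61 and 0.58 and Klf9 by 0.43. Vascular growth genes had 2 of 9 higher and 4 over the list alone (adjusted p = 0.000461, and adjusted p = 0.178 with an estimated correlation). Apln rose by 0.88 and Angpt1 by 0.60. Cholesterol synthesis genes fell, 3 of 22 over all genes and 7 over the list alone (adjusted p = 0.00233, and adjusted p = 0.454 with an estimated correlation). Cyp51, which encodes an enzyme of sterol synthesis, fell by 0.50.

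In OPCs Olig2, the transcription factor of the oligodendrocyte lineage (chromosome 16, 91225550 to 91228677), rose by 0.72 (SE 0.095, adjusted p = 1.7e-05), and the adaptor gene Shc4 by 0.69 (SE 0.092, adjusted p = 7.27e-05). The netrin receptor gene Unc5d fell by 1.15 (SE 0.22, adjusted p = 0.00323), and the homeobox gene Prrx1 fell by 0.66 (SE 0.126, adjusted p = 0.00326). Adm, which encodes the vasodilator peptide adrenomedullin (chromosome 7, 110627657 to 110629820), rose by 2.25 (SE 0.361, adjusted p = 0.000197). The level of Adm went from 2.14 ± 1.88 CPM (SD, n = 3) to 19.3 ± 3.64 (SD, n = 3) in females and from 6.11 ± 0.765 (SD, n = 3) to 17.5 ± 6.73 (SD, n = 3) in males. Adm was 1 of 6 higher HIF targets of 14 measured, with 8 over the list alone (adjusted p = 6.59e-10, and adjusted p = 0.269 with an estimated correlation). Kdm3a (0.60) and P4ha1 (0.59) rose beside it. The clock genes Bhlhe40 and Per1 rose by 1.63 (SE 0.291, adjusted p = 0.00113) and 1.59 (SE 0.352, adjusted p = 0.00761). Potassium channel genes had 4 of 26 higher and 5 over the list alone (adjusted p = 7.17e-05, and adjusted p = 0.324 with an estimated correlation). The matrix list had 2 of 10 higher and 3 over the list alone (adjusted p = 0.00443, and adjusted p = 0.454 with an estimated correlation). Tnr rose by 0.27 and Ptprz1 by 0.21. Glutamate synapse genes were called higher with a median of 0.11 and a mean of −0.01, so the median and the mean had opposite signs (adjusted p = 0.00593, and adjusted p = 0.454 with an estimated correlation).

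In oligodendrocytes Ddit4, an inhibitor of mTOR signalling that answers to stress, hypoxia and glucocorticoids (chromosome 10, 59949675 to 59951770), rose by 1.02 (SE 0.141, adjusted p = 0.000419). The level of Ddit4 went from 41.5 ± 10.4 CPM (SD, n = 3) to 92.5 ± 21.9 (SD, n = 3) in females and from 42.1 ± 10.6 (SD, n = 3) to 84.3 ± 6.17 (SD, n = 3) in males. Kdm3a rose by 0.90 (SE 0.125, adjusted p = 0.000469). Spink10 fell by 1.90 (SE 0.259, adjusted p = 0.000419), and Xrcc6, which encodes the Ku70 subunit of DNA double-strand break repair (chromosome 15, 81987833 to 82040085), fell by 0.92 (SE 0.133, adjusted p = 0.000586). HIF targets had 10 of 19 higher and 14 over the list alone (adjusted p = 1.76e-12, and adjusted p = 0.324 with an estimated correlation). Pdk1 (0.96) and Vegfa (0.64) were among them. Glucocorticoid response genes had 3 of 11 higher and 4 over the list alone (adjusted p = 0.00491, and adjusted p = 0.324 with an estimated correlation). Fkbp5 rose by 0.76 and Klf9 by 0.52 beside Ddit4. Heat shock genes had 1 of 11 lower and 3 over the list alone (adjusted p = 0.000388, and adjusted p = 0.268 with an estimated correlation). Hsph1 fell by 0.72. The markers of OPCs had 4 of 12 higher and 7 over the list alone (adjusted p = 0.000108, and adjusted p = 0.324 with an estimated correlation). Vcan, Ptprz1 and Tnr, which are on this list and on the matrix list, rose by 0.41, 0.46 and 0.33. Whether OPC markers rose within mature and within newly formed oligodendrocytes, whose proportions are given under other observations, was not tested. Potassium channel genes had 4 of 24 higher (8 over the list alone) with adjusted p = 0.000803, and adjusted p = 0.324 with an estimated correlation. Axon guidance genes had 4 of 28 higher (7 over the list alone) (adjusted p = 0.00103, and adjusted p = 0.269 with an estimated correlation).

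**Figure D4:**
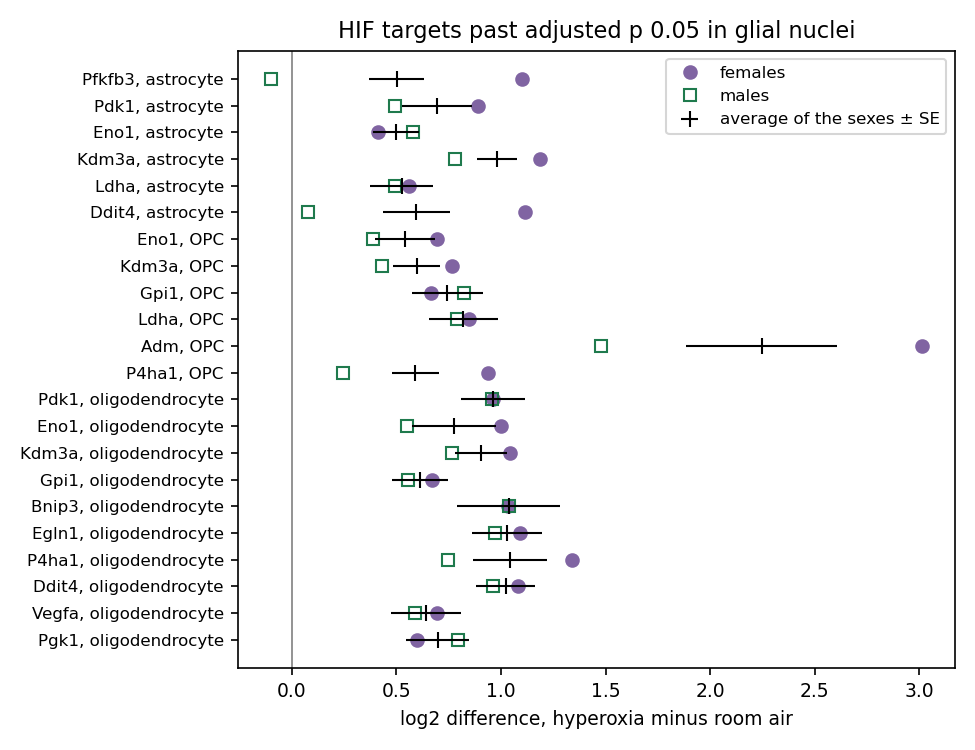
Log2 difference of the 22 called HIF targets in astrocytes, OPCs and oligodendrocytes, in females and in males. These were picked as past the threshold in the average over the same mice, which favours positive values in both sexes. The median over these 22 was 0.951 in females and 0.669 in males.

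In microglia the transcription factor gene Mef2a (chromosome 7, 67231163 to 67376456) rose by 0.50 (SE 0.068, adjusted p = 2.37e-06). The level of Mef2a went from 2542 ± 133 CPM (SD, n = 3) to 3508 ± 445 (SD, n = 3) in females and from 2890 ± 90.3 (SD, n = 3) to 4172 ± 235 (SD, n = 3) in males. Picalm, a clathrin adaptor gene, rose by 0.43 (SE 0.07, adjusted p = 0.000184), the splicing factor gene Tra2a fell by 0.64 (SE 0.109, adjusted p = 0.000272), and the prostaglandin dehydrogenase gene Hpgd fell by 0.72 (SE 0.158, adjusted p = 0.012). Interferon response and microglial activation genes were not called in microglia (adjusted p = 0.29 and 0.229, with 0 of 8 and 0 of 9 members past the threshold). In endothelial nuclei edgeR called 0 genes, with 316 at unadjusted p < 0.05, while DESeq2 called 1 and limma-voom 0. In mural and fibroblast nuclei edgeR called 0 genes, with 212 at unadjusted p < 0.05, while DESeq2 called 1 and limma-voom 0.

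Lists of mitochondrial and ribosomal genes were called lower in several classes at the preset correlation, and none with an estimated correlation. Mitochondrial transcripts had medians of −0.645 in excitatory neurons, −0.544 in inhibitory neurons, −0.527 in OPCs, −0.685 in oligodendrocytes and −0.668 in microglia, with 0 members past the threshold in each (adjusted p = 0.0495, 0.000878, 0.000726, 0.00536 and 1.99e-05, and adjusted p = 0.6 to 0.789 with an estimated correlation). The median mitochondrial percentage of counts lay below the room air mean of the same sex in 5 of 6 hyperoxia mice. Nuclear genes of oxidative phosphorylation had medians of −0.251 in excitatory neurons, where Atp5c1 fell by 0.16, and −0.223 in astrocytes (adjusted p = 0.00365 and 1.27e-05, and adjusted p = 0.786 and 0.61 with an estimated correlation). In oligodendrocytes their median was −0.33 and in microglia −0.38 (adjusted p = 2.6e-05 and 4.38e-06, and adjusted p = 0.662 and 0.627 with an estimated correlation). The ribosomal list had a median of −0.222 in excitatory neurons (adjusted p = 0.0171, and adjusted p = 0.833 with an estimated correlation). Its 2 members past the threshold there were the kinase genes Rps6ka5 and Rps6ka2, which rose by 0.36 and 0.24. The ribosomal list was also called in inhibitory neurons (median −0.208), oligodendrocytes (−0.231) and endothelial cells (−0.347), with 0 members past the threshold in each (adjusted p = 0.000388, 0.000301 and 6.59e-10, and adjusted p = 0.774, 0.76 and 0.627 with an estimated correlation). In astrocytes, OPCs and microglia it had medians of −0.165, −0.135 and −0.121 (adjusted p = 0.00155, 0.00491 and 0.0342, and adjusted p = 0.792, 0.797 and 0.833 with an estimated correlation). The single member past the threshold in these 3 was Rpl22l1 in astrocytes, which fell by 0.56 (SE 0.152, adjusted p = 0.0281).

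Other lists were not called in the neurons and macroglia. NRF2 genes had 0 of 20 members past the threshold in excitatory neurons (adjusted p = 0.553) and 0 of 18 in astrocytes (adjusted p = 0.95). In endothelial nuclei the list was called lower with 0 of 13 members past the threshold (adjusted p = 0.0485, and adjusted p = 0.61 with an estimated correlation). The p53 targets had 2 of 19 lower in excitatory neurons, Ccng1 by 0.38 and Polk by 0.22 (list adjusted p = 0.172). Interferon genes had 2 of 16 lower there, B2m by 0.37 among them (list adjusted p = 0.68). Also in excitatory neurons, reactive astrocyte genes had 1 of 8 lower (Cp by 0.68, list adjusted p = 0.578). Proliferation genes had 1 of 20 lower in the same neurons (Ccnb2 by 0.49, list adjusted p = 0.675).

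Some genes moved in many classes. Past the threshold in at least 2 classes were 416 genes higher and 243 lower, in at least 4 classes 27 and 7, and 23 genes moved in both directions. In 5 classes the higher genes were H3f3b, Mtmr2, Nav1, Ptbp2, Rbm25 and Setd5. The splicing regulator Ptbp2 rose by 0.44 in excitatory neurons, 0.34 in inhibitory neurons, 0.46 in astrocytes, 0.33 in OPCs and 0.38 in oligodendrocytes. The histone gene H3f3b rose by 0.56 in excitatory neurons, 0.70 in astrocytes, 0.64 in OPCs, 0.74 in oligodendrocytes and 0.77 in microglia. The glycolysis gene Pfkl rose by 1.07 in astrocytes, 1.03 in OPCs, 1.45 in oligodendrocytes and 0.20 in excitatory neurons. The cholesterol exporter gene Abca1 rose by 0.88 in excitatory neurons, 0.58 in oligodendrocytes and 0.55 in microglia. Spink10 fell by 0.96 in excitatory neurons and by 1.28 in astrocytes, beside its fall in inhibitory neurons and oligodendrocytes.

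In females hyperoxia raised Stac in excitatory neurons, an adaptor gene of voltage-gated calcium channels (chromosome 9, 111561437 to 111690588), by 1.28 (SE 0.137, adjusted p = 0.000914), from 5.6 ± 0.795 CPM (SD, n = 3) to 13.6 ± 1.54 (SD, n = 3). The calcium pump gene Atp2b4 rose by 0.60 (SE 0.078, adjusted p = 0.00278). Taf13 and Tbc1d2 fell by 0.80 (SE 0.116, adjusted p = 0.0059) and 0.69 (SE 0.112, adjusted p = 0.00711). Hif3a rose by 1.01, Vcan by 0.64, the calcium-activated potassium channel gene Kcnn3 by 0.73, the cadherin gene Cdh13 by 0.57, Ddit4 by 0.89 and the cystine transporter gene Slc7a11 by 0.79. In inhibitory neurons Dpp10 rose by 0.73 (SE 0.1, adjusted p = 0.00283), the calcium release channel gene Ryr3 by 0.63 (SE 0.103, adjusted p = 0.0319), and Naa16 fell by 0.67 (SE 0.133, adjusted p = 0.0494). There were 573 calls in females, 389 higher and 184 lower: 435 in excitatory neurons, 98 in astrocytes, 17 in OPCs, 11 in inhibitory neurons, 10 in oligodendrocytes and 2 in microglia, where Mef2a rose by 0.46. In endothelial nuclei edgeR called 0 genes with 191 at unadjusted p < 0.05 (DESeq2 1, limma-voom 0), and in mural and fibroblast nuclei 0 with 128 (DESeq2 0, limma-voom 0). Leaving out 1 mouse changed the count of 573 to 100 (hyperoxia female mouse 2), 99 (hyperoxia female mouse 3), 200 (room air female mouse 1), 133 (room air female mouse 2), 84 (room air female mouse 3) or 1165 (hyperoxia male mouse 3).

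In hyperoxia females the HIF target list was called higher in all 3 macroglial classes. In astrocytes Kdm3a rose by 1.19 (SE 0.139, adjusted p = 1.06e-05), the glycolysis genes Pfkp and Pfkfb3 by 1.09 (SE 0.143, adjusted p = 5.51e-05) and 1.10 (SE 0.187, adjusted p = 0.00127). Kcnip3 and Tmem47 fell by 0.80 (SE 0.134, adjusted p = 0.00114) and 0.93 (SE 0.154, adjusted p = 0.00207). The HIF targets had 3 of 19 higher there and 8 over the list alone (adjusted p = 3.7e-09, and adjusted p = 0.308 with an estimated correlation). Glucocorticoid response genes had 5 of 16 higher and 8 over the list alone (adjusted p = 1.66e-10, and adjusted p = 0.371 with an estimated correlation). Mt2 rose by 1.07 and Ddit4 by 1.11. In OPCs Adm rose by 3.01 (SE 0.567, adjusted p = 0.00558), the collagen hydroxylase gene P4ha1 by 0.94 (SE 0.161, adjusted p = 0.00553) and Nrxn2 by 0.59 (SE 0.107, adjusted p = 0.00553), and Zmym1 fell by 1.90 (SE 0.424, adjusted p = 0.0323). The OPC list had 3 of 14 higher and 7 over the list alone (adjusted p = 5.29e-12, and adjusted p = 0.308 with an estimated correlation). In oligodendrocytes the adhesion gene Cntn5 (chromosome 9, 9634223 to 10904775) rose by 1.82 (SE 0.28, adjusted p = 0.00899) and Mctp1 by 1.61 (SE 0.265, adjusted p = 0.0115). HIF targets had 2 of 19 higher and 15 over the list alone (adjusted p = 1.11e-12, and adjusted p = 0.34 with an estimated correlation). In excitatory nuclei of females the markers of striatal neurons were higher, 1 of 11 over all genes and 2 over the list alone (adjusted p = 0.0255, and adjusted p = 0.595 with an estimated correlation). Of 169 list tests in females 71 were called, 38 higher and 33 lower.

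In males hyperoxia raised Myo16 in excitatory neurons by 0.64 (SE 0.055, adjusted p = 2.45e-05) and Epm2a, which encodes the glycogen phosphatase laforin (chromosome 10, 11342691 to 11459664), by 0.68 (SE 0.074, adjusted p = 0.000222). Ostc fell by 0.85 (SE 0.085, adjusted p = 0.000101) and Wdr78, a gene of ciliary dynein, fell by 0.69 (SE 0.085, adjusted p = 0.000666). Genes of the unfolded protein response fell, 7 of 20 over all genes and 9 over the list alone (adjusted p = 0.000276, and adjusted p = 0.493 with an estimated correlation). Hsp90b1 fell by 0.49, Pdia6 by 0.49 and Pdia4 by 0.75. Cholesterol synthesis genes had 5 of 23 lower and 9 over the list alone (adjusted p = 0.00273, and adjusted p = 0.739 with an estimated correlation), among them Msmo1, which fell by 0.52. Myelin genes had 6 of 24 lower and 8 over the list alone (adjusted p = 0.000373, and adjusted p = 0.739 with an estimated correlation). Mog fell by 1.28 and Cldn11 by 1.20. The markers of striatal neurons had 3 of 11 lower in excitatory nuclei of males (adjusted p = 0.00588, and adjusted p = 0.739 with an estimated correlation). In astrocytes of males their median was −0.789 with 0 of 8 past the threshold and 3 lower over the list alone (adjusted p = 0.000373, and adjusted p = 0.404 with an estimated correlation). There were 1496 calls in males, 824 higher and 672 lower: 1321 in excitatory neurons, 82 in astrocytes, 39 in OPCs, 30 in inhibitory neurons, 13 in microglia and 11 in oligodendrocytes. Leaving out 1 mouse changed the count of 1496 to 358 (hyperoxia male mouse 1), 785 (hyperoxia male mouse 2), 2412 (hyperoxia male mouse 3), 719 (room air male mouse 2) or 379 (room air male mouse 3). The order of the sexes depended on the fit: with only the groups compared in the model the females had 1378 calls and the males 157.

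Glia and inhibitory neurons of males gave fewer calls, with the largest number in astrocytes. In inhibitory neurons the Wnt antagonist gene Dkk2 (chromosome 3, 132085266 to 132180304) rose by 2.04 (SE 0.325, adjusted p = 0.0146) and Spink10 fell by 1.16 (SE 0.146, adjusted p = 0.00059). In astrocytes the centriole gene Cep128 (chromosome 12, 90998490 to 91384455) rose by 1.31 (SE 0.159, adjusted p = 0.000725), Fam171a1 by 0.91 (SE 0.135, adjusted p = 0.000725), Kdm3a by 0.78 (SE 0.132, adjusted p = 0.00158) and Gfap by 0.89 (SE 0.215, adjusted p = 0.0429). Kcnip3 and Dusp6 fell by 0.88 (SE 0.139, adjusted p = 0.000797) and 1.17 (SE 0.27, adjusted p = 0.0291). In OPCs the metalloprotease gene Adamts9 (chromosome 6, 92772699 to 92944450) rose by 1.10 (SE 0.176, adjusted p = 0.00145), Sema5b by 0.61 (SE 0.109, adjusted p = 0.0071). Pik3r3 and Dpysl3 fell by 0.71 (SE 0.152, adjusted p = 0.027) and 0.50 (SE 0.112, adjusted p = 0.0393). In oligodendrocytes Dgke rose by 1.23 (SE 0.191, adjusted p = 0.0041), Gng4 by 1.11 (SE 0.188, adjusted p = 0.00917) and Ddit4 by 0.96 (SE 0.196, adjusted p = 0.0482). Spink10 and Xrcc6 fell by 2.99 (SE 0.403, adjusted p = 0.00086) and 1.03 (SE 0.183, adjusted p = 0.0123). HIF targets were higher in oligodendrocytes, 1 of 19 over all genes and 10 over the list alone (adjusted p = 1.85e-07, and adjusted p = 0.539 with an estimated correlation). In OPCs they were higher with 0 of 14 over all genes and 5 over the list alone (adjusted p = 0.000854, and adjusted p = 0.739 with an estimated correlation). In astrocytes of males the list was not called, with 1 of 19 higher over all genes, and 2 higher and 1 lower over the list alone (adjusted p = 0.136). In microglia Mef2a rose by 0.53 (SE 0.096, adjusted p = 0.00214) and Zc3h6 by 1.69 (SE 0.36, adjusted p = 0.0167). Tra2a and Atp6v0c fell by 0.72 (SE 0.156, adjusted p = 0.0167) and 0.77 (SE 0.171, adjusted p = 0.0213). In endothelial nuclei edgeR called 0 genes with 319 at unadjusted p < 0.05 (DESeq2 2, limma-voom 0), and in mural and fibroblast nuclei 0 with 219 (DESeq2 0, limma-voom 0). Of 169 list tests in males 57 were called, 25 higher and 32 lower.

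Most genes that moved in females had the same sign in males. Of the 435 female calls in excitatory neurons 399 (91.7%) had the same sign in males, and 99 higher and 69 lower genes were called in both sexes, where independent calls would give 11.3 and 5.59. Myo16, Ostc, Taf13 and Hif3a were among the excitatory genes with the same sign in both. In astrocytes 94 of 98 female calls (95.9%) had the same sign in males, with 22 higher and 6 lower called in both, Kdm3a and Kcnip3 among them. The 2 sexes share the fit but no mice. Across all genes the log2 differences of females and males had a correlation of 0.417 in excitatory neurons and 0.329 in astrocytes.

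The change under hyperoxia differed between the sexes for 1 gene, Vwc2 in excitatory neurons, which encodes a secreted antagonist of bone morphogenetic proteins (chromosome 11, 11113868 to 11269295). Vwc2 was at 21.8 ± 2.70 CPM (SD, n = 3) in hyperoxia females against 12.6 ± 1.38 (SD, n = 3) in room air females. It was at 14.9 ± 1.72 (SD, n = 3) in hyperoxia males against 20.6 ± 2.36 (SD, n = 3) in room air males. The difference, male change minus female change, was −1.27 (SE 0.169, adjusted p = 0.0171). Vwc2 was not called with equal numbers of nuclei per subtype (difference −1.07, adjusted p = 0.483) or with the striatal share as a covariate (difference −1.22, adjusted p = 0.277), and was not tested when genes of other cells were left out. With every mouse thinned to the same number of nuclei Vwc2 was not called in excitatory neurons either, and the 1 call there was a different one. In room air Vwc2 was higher in males than in females by 0.72 (SE 0.12, adjusted p = 0.0162). In inhibitory neurons, astrocytes, OPCs, oligodendrocytes, microglia, endothelial and mural or fibroblast nuclei edgeR called 0 genes, with 619, 524, 452, 450, 187, 207 and 131 at unadjusted p < 0.05. DESeq2 called 29 genes in all, 28 of them in excitatory neurons and 1 in endothelial nuclei, and limma-voom called 7, all in excitatory neurons. The count of 1 became 2 without hyperoxia female mouse 1, 0 without hyperoxia female mouse 2, hyperoxia female mouse 3, hyperoxia male mouse 1 or room air male mouse 3. It became 4 without room air female mouse 2, 16 without hyperoxia male mouse 2, 19 without hyperoxia male mouse 3 and 36 without room air male mouse 1. Kdm3a in astrocytes, higher by 1.19 in females and 0.78 in males, had an adjusted p for the difference of 0.988.

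Among the lists 26 of 169 differed between the sexes at the preset correlation, 7 higher and 19 lower in males relative to females, and each had adjusted p = 0.961 with an estimated correlation. The count of 26 became 15 without room air female mouse 1, 54 without room air female mouse 3, 46 without hyperoxia male mouse 2, 43 without room air male mouse 1 and 40 without room air male mouse 2. The markers of striatal neurons had a median difference of −0.659 in excitatory nuclei, −0.799 in inhibitory nuclei and −1.05 in astrocytes (adjusted p = 4.67e-07, 0.000348 and 0.00242). In these 3 tests 0 members passed the threshold over all genes, and 7 of 11, 1 of 11 and 2 of 8 were lower over the list alone. HIF targets and glucocorticoid response genes in astrocytes had median differences of −0.384 and −0.609 (adjusted p = 0.000213 and 2.37e-05), with 0 members over all genes and 2 each over the list alone. Cholesterol synthesis genes in excitatory neurons had a median difference of −0.201 with 0 of 23 past the threshold (adjusted p = 0.000287). Proliferation genes in OPCs had a median difference of 0.348 with 0 of 19 past the threshold (adjusted p = 0.00467).

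In room air edgeR called few genes between male and female mice, apart from those of the sex chromosomes used as a check. The number depended on the method, with 211 calls in DESeq2 and 698 in limma-voom. In excitatory neurons Filip1l, a gene tied to the cytoskeleton (chromosome 16, 57353277 to 57572804), was higher in males by 0.85 (SE 0.115, adjusted p = 0.00281). Also in excitatory neurons the cytokine receptor gene Il31ra was higher by 1.43 (SE 0.203, adjusted p = 0.00404), and Ggps1 and Jpx, a neighbour of Xist on the X chromosome, were lower with −0.34 (SE 0.056, adjusted p = 0.0138) and −0.37 (SE 0.07, adjusted p = 0.0333). In inhibitory neurons Cmss1 (chromosome 16, 57301999 to 57606867) was higher by 0.58 (SE 0.102, adjusted p = 0.0129), and because Filip1l lies within Cmss1 it is uncertain which of the 2 genes the reads came from. In astrocytes Azin1, which regulates polyamine synthesis (chromosome 15, 38487430 to 38519294), was higher in males by 1.08 (SE 0.166, adjusted p = 0.00406), with 123 ± 15.2 CPM (SD, n = 3) in females and 260 ± 29 (SD, n = 3) in males. The potassium channel gene Kcnn2 was higher by 0.72 (SE 0.114, adjusted p = 0.000727), the glucocorticoid target Tsc22d3 by 1.11 (SE 0.233, adjusted p = 0.0444), and Ccdc190 was lower with −0.84 (SE 0.159, adjusted p = 0.0091). In OPCs Kcnip3 was lower in males with −0.53 (SE 0.111, adjusted p = 0.0265). For each of these genes 3 of 3 room air males lay beyond the female mean. Jpx and Tsc22d3 were among those not called with a block for the mouse number. Glucocorticoid response genes were higher in astrocytes of males, 1 of 16 over all genes and 5 over the list alone (adjusted p = 2.95e-08, and adjusted p = 0.999 with an estimated correlation).

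There were 55 calls between the sexes in room air, 50 higher and 5 lower in males, 39 of them in excitatory neurons and 10 in astrocytes. With a block for the mouse number 45 genes were called, 26 of them among the 55. In microglia edgeR called 0 genes, with 260 at unadjusted p < 0.05, while DESeq2 called 1 and limma-voom 1. The count of 55 became 13 without room air female mouse 1, 20 without room air female mouse 2 and 14 without room air female mouse 3. It became 181 without hyperoxia male mouse 3, 686 without room air male mouse 1, 26 without room air male mouse 2 and 15 without room air male mouse 3. The astrocyte markers were lower in males in inhibitory neurons, with a median of −0.387 and 0 of 15 past the threshold, and in oligodendrocytes, with −0.367 and 0 of 13 (adjusted p = 0.000338 and 0.00238, and adjusted p = 0.999 and 0.967 with an estimated correlation). Of 169 list tests 9 were called, 5 higher and 4 lower, and 22, 36, 31, 24 and 25 were called without room air female mouse 1, room air female mouse 3, or room air male mouse 1, 2 or 3.

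Neuronal subtypes were also compared in the average over the sexes. L6 CT neurons had 1117 calls (657 higher, 460 lower), layer 2/3 intratelencephalic (L2/3 IT) neurons 1051 (580 and 471), a pool of 3 IT clusters whose markers did not settle the layer 1004 (573 and 431) and layer 5 extratelencephalic neurons 488 (337 and 151). Among inhibitory subtypes the Pvalb group had 118 (91 and 27), Sst neurons 40, Vip neurons 8 and Lamp5/Sncg neurons 1. Subtypes differed in precision as well, with a median SE of 0.124 in L6 CT neurons and 0.242 in Lamp5/Sncg neurons. These counts therefore do not rank the subtypes by response. Over the subtypes there were 4458 calls in the average. There were 2343 without hyperoxia female mouse 2, 2356 without hyperoxia female mouse 3, 2911, 2690 and 2567 without room air female mouse 1, 2 or 3, 2441 without hyperoxia male mouse 1 and 2747 without room air male mouse 3. The change differed between the sexes for Rftn1, a lipid raft gene, in L6 CT neurons (difference −3.54, SE 0.541, adjusted p = 0.00944), with 2.71 in females and −0.83 in males. It also differed for the glutamate receptor gene Grm8 in Lamp5/Sncg neurons (difference −1.78, SE 0.318, adjusted p = 0.0442), with 0.99 in females and −0.80 in males.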

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

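The results listed here were picked by rules on the tables after the data were seen. All splits of mice into other groups were planned before their results were seen, while the tests with the mitochondrial share as a covariate were chosen after the result was seen.

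The difference between the sexes in excitatory neurons was the single gene Vwc2, with −1.27 (SE 0.169). With equal numbers of nuclei of each excitatory subtype in every mouse the difference of Vwc2 was −1.07 (SE 0.234, adjusted p = 0.483), and with the striatal share of each mouse as a covariate it was −1.22 (SE 0.224, adjusted p = 0.277). Both kept the sign and most of the size and both lost the threshold, so an effect of hyperoxia that depends on sex, shares of subtypes and dissection cannot be told apart for Vwc2. Over all mice Vwc2 was at 225 CPM in inhibitory neurons and 17.3 CPM in excitatory neurons, and when genes that count as coming from other cells were left out it was not tested in excitatory neurons. Within L6 CT neurons alone the difference of Vwc2 was −1.14 (SE 0.201, adjusted p = 0.0562). It was −1.387 (SE 0.51) in L2/3 IT neurons and −0.891 (SE 0.286) in layer 6b neurons. In the pool of 3 IT clusters it was −0.395 (SE 0.537), and in layer 5 extratelencephalic neurons −0.08 (SE 0.296). None of these subtypes passed the threshold. Exchanging sex labels within each treatment gave a count as large as the real count of 1 in 12 of 25 splits, with 353 as the highest other, so chance cannot be excluded for that count. Of the 24 other splits 2 parted the room air mice by their mitochondrial share, and they gave 283 and 353 calls. Another split, which did not part them so, gave 154 calls. With the mitochondrial share as a covariate the real count was 1.

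In neuronal subtypes 2 genes differed between the sexes, Rftn1 in L6 CT neurons (−3.54) and Grm8 in Lamp5/Sncg neurons (−1.78). Exchanging sex labels within each treatment gave a count as large as 2 in 13 of 25 splits, with 410 as the highest other, so chance cannot be excluded for the count. The cause of either difference was not tested.

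In the list tests 26 lists differed between the sexes, the markers of striatal neurons first. Exchanging sex labels gave as many in 21 of 25 splits, with 73 as the highest other, so chance cannot be excluded. Striatal nuclei made up 0.58%, 3.21% and 4.14% in the hyperoxia females and 1.3%, 0.64% and 0.64% in the hyperoxia males, and the cause of the list differences was not tested.

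Clusters kept out of the tests were largest in hyperoxia females, where mixed clusters held 11.1% of nuclei against 7.54% in room air females, 6.86% in hyperoxia males and 6.91% in room air males. Unnamed clusters held 4.26% of the nuclei of hyperoxia females against 2.17%, 3.42% and 3.08% in the same order. An unnamed cluster of 108 nuclei, led by Ano1, Zic1, Isl1 and Prlr, held 66 nuclei of hyperoxia females, 14 of room air females, 22 of hyperoxia males and 6 of room air males. The larger unnamed clusters held 395 and 372 nuclei. The cluster of 395, with astrocyte markers and led by Thbs4 and Veph1, held 101, 73, 108 and 113 nuclei in that order. The cluster of 372, with the proliferation genes Top2a and Mki67, held 113, 63, 106 and 90. What these nuclei are was not tested.

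For the average over the sexes, exchanging treatment labels within each sex gave 4441 calls for the real split and at most 13 for the others. With 1 of 25 splits as large, the share was the smallest that 25 splits allow and lay under 0.05. This argues against a chance split of the mice for the calls. The exchange cannot tell the oxygen from anything else that mice of 1 treatment shared. The subtype calls behaved in the same way, with 4458 for the real split, 26 as the highest other and 1 of 25 splits as large. For the lists the real split gave 73, the highest other gave 74, and 2 of 25 splits were as large, so chance cannot be excluded for the count of lists. Within a sex there are 10 splits of 6 mice, too few for a share under 0.05. They gave 573 in females (1 of 10 as large, highest other 5), 1496 in males (1 of 10, highest other 121) and 55 between the sexes in room air (1 of 10, highest other 2). The lists gave 71 in females (1 of 10, highest other 55), 57 in males (3 of 10, highest other 77) and 9 in room air (10 of 10, highest other 56). Subtype calls gave 545 in females (1 of 10, highest other 8) and 1220 in males (1 of 10, highest other 60).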

How the results depend on the processing

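Of 6809 re-estimates of named genes over all settings and left-out mice, 5580 kept the label of the first estimate, 1228 were weaker and 1 was reversed: Kcnip4 in OPCs of males, 0.50 with all nuclei, was −0.07 with every mouse thinned to the same number of nuclei. Genes absent from a fit do not enter these counts. With genes of other cells left out, the 131 named genes still measured in the average all kept their label, and those dropped were not scored. All settings reuse mice in which the genes were picked. The mitochondrial covariate, the shares without striatal and immature neurons and the fit without the 2 mice of highest mitochondrial share were chosen after the result was seen.

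The female count of 573 became 1437 with limma-voom, 1094 without an expression filter, 339 with thinned nuclei, 1378 with only the groups compared, 1219 with the mitochondrial covariate and 172 without the 2 mice of highest mitochondrial share. The male count of 1496 became 3047 with limma-voom, 157 with only the groups compared and 2373 with the covariate. The average of 4441 became 2941 with thinned nuclei. The difference count of 1 became 29 with DESeq2, 7 with limma-voom, 64 without a filter, 5 with nuclei of at most 1% mitochondrial counts, 0 with genes of other cells left out and 10 without the 2 mice. The room air count of 55 became 211 with DESeq2, 698 with limma-voom, 305 without a filter, 110 with the stricter nuclei, 83 with the covariate and 259 without the 2 mice.

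Called lists numbered 71 in females, and 0 with an estimated correlation, 1 with fry and 44 with the stricter nuclei. In males the 57 became 0 and 4 with an estimated correlation and fry, in the average the 73 became 0 and 23, in the difference the 26 became 0 and 0, and in room air the 9 became 0 and 0. The subtype difference count of 2 became 19 with DESeq2. With shares taken among neurons and among other nuclei separately, 1 class passed in the average (oligodendrocytes, logit −0.339, exact p = 0.005, adjusted 0.04) and 1 in the difference (excitatory neurons, 0.607, exact p = 0.005, adjusted 0.04). Without striatal and immature neurons among the neurons 1 class passed in the average and 0 in the difference (excitatory neurons, 0.314, adjusted 0.06).

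A block for the mouse number gave 410 calls in females, 1257 in males, 4110 in the average, 6 in the difference and 45 in room air, 48 lists in the difference and 18 in room air, and 11 subtype calls in the difference. Of the 55 room air calls 26 were kept, and Jpx (adjusted p = 0.0723) and Tsc22d3 (adjusted p = 0.0521) were not. Among the named genes 3 in room air, 10 in females, 13 in the average and 2 in males were weaker with the block. The mice of equal number are different animals. Of 18 pairs of equal number all 9 among room air females, hyperoxia males and room air males correlated above 0.1 (0.106 to 0.746), and all 9 with a hyperoxia female were below 0 (−0.349 to −0.00282). In those 3 groups the mice 1 and 2 of unequal number also correlated (0.248 to 0.462), and mouse 3 stood apart from both. The median was 0.0516 for equal numbers and 0.0244 for others, and 3 of 12 mice correlated best with their own number. Mouse 3 also had the lowest median mitochondrial percentage in room air females, hyperoxia males and room air males (0.251, 0.119 and 0.154). Hyperoxia females ranged over 0.202 to 0.28. The correlations alone cannot tell a pairing by number from a shared difference in mitochondrial percentage, so whether the numbers pair the mice outside hyperoxia females is left open.

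Leaving out 1 mouse at a time gave 84 to 1165 calls in females, 358 to 2412 in males, 2663 to 5426 in the average, 0 to 36 in the difference and 13 to 686 in room air. Lists ranged over 58 to 78 in females, 40 to 76 in males, 54 to 80 in the average, 15 to 54 in the difference and 9 to 36 in room air. Subtype calls ranged over 107 to 1019, 170 to 2191, 2343 to 6449 and 2 to 34 in females, males, the average and the difference. The number of classes with a changed share ranged over 0 to 0 in the average and 0 to 1 in the difference, and for subtypes over 0 to 0 in both.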

Other observations

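Genes that rose in hyperoxia were longer than the genes tested. In excitatory neurons the called genes that rose had a median length of 71.2 kb, those that fell 22.7 kb and all genes tested 25.2 kb, and in inhibitory neurons these were 166, 27.1 and 28.3 kb. In OPCs they were 134, 45.8 and 33.7 kb, so that the called genes that fell were longer than all genes there. Myo16 and Dpp10 are among the long genes that rose. The Spearman correlation of log2 difference with gene length in the average was 0.266 in excitatory neurons, 0.247 in inhibitory neurons, 0.26 in astrocytes, 0.203 in OPCs, 0.259 in oligodendrocytes and 0.15 in microglia. Between male and female mice in room air it was 0.157, 0.143, 0.0666, −0.00384, 0.0501 and 0.00176 in the same order. Lengths were known for 90.8% to 98% of the genes tested.

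Oligodendrocyte nuclei were divided into mature ones with myelin genes such as Mog and Mag and newly formed ones with Bcas1, Enpp6 and Gpr17. Mature nuclei were 40.4% to 50.8% of the oligodendrocytes of the hyperoxia mice and 48.7% to 56.5% of those of the room air mice. No test of that share was made.

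The patterns below were seen in the data and then tested on the same data, and the tests with the mitochondrial share as a covariate, those of neuronal markers within each glial class and those over all measured HIF targets were chosen after the result was seen. The first is the rise of HIF targets in astrocytes, OPCs and oligodendrocytes. Over all measured targets the median was 0.243 in astrocytes (17 of 19 positive), 0.594 in OPCs (13 of 14) and 0.904 in oligodendrocytes (16 of 19). The 22 called members had a median of 0.72, which their choice by the threshold in the same mice largely sets. RNA from neurons in glial nuclei should raise the markers of excitatory neurons, which went both ways over the 3 classes (median −0.0286, quartiles −0.24 and 0.447). More neuronal RNA is argued against in OPCs and oligodendrocytes, where 7 markers each were measured. Their upper quartiles of 0.23 and 0.373 lay below the medians of all targets. In astrocytes the upper quartile of 0.502 lay above that median, so neuronal RNA stays open there. RNA quality as read from the mitochondrial share is argued against as a full explanation, because with it as a covariate the median over all measured targets was 0.294 in astrocytes, 0.557 in OPCs and 0.947 in oligodendrocytes (0.816 for the called targets). Other proportions of mature and newly formed oligodendrocytes are argued against as a full explanation, because the targets rose within each kind. Of all measured targets 17 of 18 were positive within mature and 15 of 17 within newly formed nuclei. Their median was 0.762 within mature and 0.77 within newly formed nuclei, against 0.839 and 0.904 for the same genes in the whole class. The lower quartiles of 0.324 and 0.432 were under the limit set for this test, so a part from proportions stays open. The called targets, with 0.776 as the lower median, were picked in the same mice and do not decide how large that part is. The cause may lie in the exposure or in the time after it, and was not tested. The time between exposure and death, and the air in it, are not given in the sources used here.

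The second pattern is that of gene length. With the mitochondrial share as a covariate the correlation fell in each of the 6 classes, to 0.188, 0.175, 0.185, 0.125, 0.179 and 0.0733 in the order above. It kept 0.5 or more of its value in 5 of 6 classes. Without genes of other cells it did so in 6 of 6 classes, and with the median UMI count as a covariate in 6 of 6. RNA quality as read from the mitochondrial share, RNA from other cells and depth per nucleus are thus argued against as full explanations. Part of the pattern goes with the mitochondrial share. Slower or longer transcription of long genes, or a difference in how much unspliced RNA the nuclei held, could give the same pattern, and the cause was not tested.

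The third pattern is Vwc2 in excitatory neurons, weighed above, whose difference of −1.07 with equal subtypes and −1.22 with the striatal covariate leaves its source open.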
